A study of Homo sapiens with 8 samples.

How the data were processed

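RNA-seq was carried out on LNCaP-FGC cells, an androgen-dependent human prostate carcinoma line, after 24 h with the solvent DMSO, with I-CBP112 (an inhibitor of the bromodomains of the coactivators p300 and CBP), with A-485 (an inhibitor of their catalytic acetyltransferase site) or with both compounds. Total RNA was extracted with Trizol and treated with DNase, and libraries were made with a kit from New England Biolabs, per the labels' protocols. Each of the 4 groups held 2 libraries, numbered 1 and 2. Doses were not given in the sources used here. The labels do not say that libraries of the same group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

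The authors' deposited values formed 1 table of 81591 transcripts and 8 libraries. The submitters' processing notes name STAR, Cufflinks, DESeq, DESeq2 and the builds hg19 and GRCh37. Their versions and the role of each are not given in the sources used here. The table was named as counts, but 78.3% of its values were not whole numbers, and the low values of long transcripts were multiples of a step that fell with transcript length. The deposited values were therefore treated as FPKM (fragments per kilobase of transcript and per 1e+06 normalizing fragments). In each library the step of 1 fragment was estimated from transcripts of at least 3000 bases (36 to 46 genes per library, tolerance 0.05). Between 83% and 91.3% of the low values were then whole multiples of it, within 0.1 of a fragment. The step gave the number of fragments by which the FPKM had been normalized and, with transcript lengths, the approximate number assigned to the transcripts of the table. The design fixed beforehand had assumed counts and named a count model, with limma on log2(value + 1) where the values proved to be normalized. The limma test was used.

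Transcripts were assigned to genes by their Ensembl identifiers, without version, in release 29 of the GENCODE annotation, which follows GRCh38 rather than the submitters' build. It served only for gene names, transcript lengths and GC content, and genome positions are not used here. Of the transcripts, 74209 (91.0%) matched and held 95.7% to 96.6% of the FPKM of each library. They were summed to 19431 genes. Each library was scaled to a total of 1e+06 and then by a trimmed mean of log ratios, with 30% of the ratios and 5% of the levels trimmed. Genes were tested where the scaled value reached 1 in at least 2 libraries, which left 11871 genes. On the FPKM as deposited, the median gene shifted against DMSO by a log2 fold change of 0.05 with I-CBP112, 0.37 with A-485 and 0.61 with both, by 0.55 between both and I-CBP112, 0.23 between both and A-485, 0.33 between A-485 and I-CBP112, and by 0.20 in the interaction. After scaling these medians lay between 0.00 and 0.05, and changes are given relative to them.

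Genes were tested with limma 3.58.1 in R 4.3.3 on log2(scaled FPKM + 1), with 1 mean per group, a trended and robust estimate of the spread shared by the 4 groups (4 residual degrees of freedom), and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The pseudocount of 1 understates the fold change of genes with low values. The 7 comparisons were each treatment with DMSO, both compounds with each alone, A-485 with I-CBP112, and the interaction, which is the log2 change with both compounds minus the sum of the changes with each. Standard errors follow the ± sign, and each group mean rests on 2 libraries. Gene lists were tested with camera in limma at a preset correlation of 0.01, two-sided and adjusted over the lists with at least 3 measured members, and again with a correlation estimated per list. That second version rests on the 4 residual degrees of freedom, so its p can rise even where the estimated correlation lies below 0.01. For the MYC and ribosome biogenesis list with A-485 the estimate was -0.0125, and adjusted p went from 3.61e-07 to 0.04997 (camera). A call lost with an estimated correlation is therefore not shown to be lost through correlation between genes. This version was run without the replicate block only. Of 27 lists (618 genes), 26 were tested. They covered androgen-induced, androgen-repressed and glucocorticoid-responsive genes, prostate transcription factors, luminal secretory metabolism, lipid synthesis, MYC and ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, the cell cycle, p53, ATF4, the unfolded protein response, hypoxia, CREB, interferon, NF-kB, acetylation enzymes, bromodomain proteins, apoptosis, and neuroendocrine, basal and stromal markers. Some lists share members, so their calls are not independent. ATF3 was in the ATF4 and CREB lists, and XBP1 in the prostate transcription factor and unfolded protein response lists. FKBP5 was in the androgen activity score and glucocorticoid-responsive lists. The list of blood and immune cell markers was not tested, because CD68 was its only measured gene.

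Named genes followed a rule. It took the 8 that rose most and the 8 that fell most in each comparison with DMSO, and 5 of each in the others, among genes that passed the test, had a mean scaled FPKM of at least 5 and moved the same way in both same-numbered pairs. The rule had been written for CPM. It added a panel of 12 genes (KLK3, KLK2, TMPRSS2, FKBP5, MYC, CCND1, EP300, CREBBP, HEXIM1, CDKN1A and 2 more) and, for lists compared with DMSO, up to 2 rising and 2 falling members with the lowest p. Other genes are named where a count was 5 or fewer, or as interaction genes, together with TM4SF1, and these were chosen after their values were seen. Some genes that met the rule, these 2 among them, are not reported here, while counts include them. The comparisons, the model without replicate block, the gene lists, this rule and the alternatives listed below as fixed beforehand were chosen before the data were examined.

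Same-numbered libraries share a prefix in their column names. Their deviations from the group means correlated across genes with r from 0.146 to 0.424 over the 6 pairs of groups, so the numbers were taken to pair the samples. A fit with the replicate number as a block had 3 residual degrees of freedom. It is given where it changes a call or moves a count of genes called over all genes by over 1.5 times. Counts with p adjusted over the members of a list alone are without the block unless stated. The code was tested on simulated libraries with gene means from the DMSO libraries and changes set in the A-485 libraries (11425 genes). The spread and the replicate effect were set rather than taken from the data, so the shares below need not hold for the data. Of 100 genes changed by a log2 fold change of 1, 52% were called, or 58% with the block, and all 100 changed by 2 were called, with 9 and 10 false calls. Alternatives fixed beforehand were other scalings (median of ratios, upper quartile), no filter or a mean of at least 5, the replicate block, each library left out, only the 2 groups compared, a minimum log2 change of 1, isoforms tested singly, the estimated correlation and fry. Alternatives added after seeing the data were the FPKM as deposited, pseudocounts of 0.1 and 5, voom on approximate fragments with and without the block, library weights, and the block with a correction for transcript length and GC content (loess, span 0.3). Tables were handled with pandas 2.3.3 in Python 3.11.15, and limma used statmod 1.5.0.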

Results

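The 8 RNA-seq libraries came from LNCaP-FGC cells, a subline of a prostate carcinoma that needs androgen for growth. The series asked what blocking the bromodomain and the acetyltransferase site of p300 and CBP does to transcription, singly and together. The FPKM of a library summed to between 696917 and 808443 in replicate 1 and to between 181486 and 408673 in replicate 2. The replicate 1 libraries held an estimated 15.9 to 28.1 M fragments (M for 1e+06) on the transcripts of the table, which was 90.7 to 99.2% of the fragments they had been normalized by. In replicate 2 these were 4.44 to 13.5 M fragments and 21.5 to 49.4%. Between 8061 and 11152 genes exceeded an FPKM of 1 per library.

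With I-CBP112 alone, no single gene passed the test against DMSO. The level of KLK3, which encodes the prostate-specific antigen, was 2099 scaled FPKM with DMSO and 1092 with I-CBP112, a log2 fold change of -0.94 ± 0.18 (n = 2 per group; limma, adjusted p = 0.221). The log2 fold change was -1.10 ± 0.26 for the related kallikrein KLK2 and -0.87 ± 0.20 for the protease gene TMPRSS2, and HEXIM1, an inhibitor of the elongation factor P-TEFb, was at 0.93 ± 0.17, none passing (limma, adjusted p from 0.218 to 0.295). Other panel genes lay closer to 0, at -0.45 ± 0.20 for MYC, -0.41 ± 0.17 for FKBP5 and -0.39 ± 0.31 for CDKN1A. Values of -0.14 ± 0.17 for CCND1, 0.19 ± 0.22 for EP300 and 0.22 ± 0.29 for CREBBP followed, and none of these 6 passed (limma, adjusted p from 0.443 to 0.813). Limma called 0 of 11871 genes without and with the replicate block, although 1317 and 2172 had an unadjusted p under 0.05, where 594 would be expected by chance. Voom on approximate fragments called 0 without the block and 383 with it.

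As groups, the genes of G1/S and DNA replication were lower with I-CBP112. All 29 measured members lay below 0 (median -0.54), with none called over all genes. Adjusted over the list alone 10 were lower, or 16 so adjusted with the replicate block (camera, adjusted p = 1.38e-12, and adjusted p = 0.148 with an estimated correlation). Targets of ATF4, the transcription factor of the integrated stress response, were lower (median -0.39, camera, adjusted p = 8.42e-07, and adjusted p = 0.222 with an estimated correlation). So were the chaperones and unfolded protein response genes of the endoplasmic reticulum (median -0.35, camera, adjusted p = 8.42e-07, and adjusted p = 0.148 with an estimated correlation). Adjusted over the list alone, 0 ATF4 targets and 2 endoplasmic reticulum genes were lower, or 10 and 6 with the block. The glucocorticoid-responsive genes shared with androgen were lower by camera too, with 6 of 14 adjusted over the list alone (median -0.28, camera, adjusted p = 0.000453, and adjusted p = 0.222 with an estimated correlation). Camera called 15 of the 26 lists, 5 higher and 10 lower, and 0 with an estimated correlation. The others lower were the G2/M (0.000605), p53 (0.00406), other androgen-induced (0.00743), androgen activity score (0.0135), prostate transcription factor (0.0254) and ribosomal protein (0.0294) lists, with the camera adjusted p in brackets. Those higher were the androgen-repressed (0.0140), fatty acid synthesis (0.0179), bromodomain protein (0.0259), cholesterol (0.0331) and acetylation enzyme (0.0331) lists. With an estimated correlation the adjusted p of these 11 lists ran from 0.222 to 0.567. The G1/S, ATF4, endoplasmic reticulum and glucocorticoid calls held with any 1 library left out. Each of the other 11 was lost without at least 1 DMSO or I-CBP112 library, with adjusted p up to 0.896 for the ribosomal proteins without I-CBP112 replicate 1. Without DMSO replicate 1, 2 genes were called, GYG2 and RSRP1, both higher.

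A-485 alone lowered many androgen-induced genes. KLK3 fell from 2099 to 603 scaled FPKM, a log2 fold change of -1.80 ± 0.18 (n = 2 per group; limma, adjusted p = 0.00499). KLK2, TMPRSS2 and FKBP5, a co-chaperone of steroid receptors, fell too. Their log2 fold changes were -2.01 ± 0.26 for KLK2, -1.30 ± 0.20 for TMPRSS2 and -0.97 ± 0.17 for FKBP5 (limma, adjusted p from 0.0102 to 0.0245). The MYC proto-oncogene fell as well (-1.92 ± 0.20; limma, adjusted p = 0.00499). HEXIM1 rose by 0.91 ± 0.17 (limma, adjusted p = 0.0301). The cyclin gene CCND1 (-0.61 ± 0.17; limma, adjusted p = 0.0834) and the cell cycle inhibitor CDKN1A (-0.87 ± 0.31; 0.129) were not called, but were with the replicate block (adjusted p = 0.0277 and 0.0118). The targets' own genes EP300 (0.68 ± 0.22) and CREBBP (0.72 ± 0.29) were not called either way. With 1 library left out their log2 fold changes ranged from 0.40 to 0.93 and from 0.27 to 1.16.

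The genes that fell most with A-485 were TRIM49D1, a member of a multigene family whose value is uncertain, CHAC1, a glutathione-degrading enzyme induced by ATF4, the prostein gene SLC45A3, the nicotinic receptor subunit CHRNA2, the calpain CAPN5, the metalloprotease ADAMTS1, the calcium-binding protein S100P and C1orf116. Their log2 fold changes were -3.38 ± 0.20 for TRIM49D1, -3.15 ± 0.22 for CHAC1, -3.11 ± 0.23 for SLC45A3 and -2.84 ± 0.28 for CHRNA2. For the rest they were -2.81 ± 0.26 for CAPN5, -2.69 ± 0.30 for ADAMTS1, -2.60 ± 0.21 for S100P and -2.53 ± 0.20 for C1orf116 (limma, adjusted p from 0.00169 to 0.00638). Those that rose most were PILRB, MT3, NAIP, AMIGO3, TTLL3, AHSA2P, DPP3 and ZNF780B, at 2.50 ± 0.30 for PILRB, 2.26 ± 0.34 for MT3, 2.09 ± 0.21 for NAIP and 2.08 ± 0.37 for AMIGO3. Further values were 2.04 ± 0.26 for TTLL3, 1.99 ± 0.39 for AHSA2P, 1.94 ± 0.25 for DPP3 and 1.81 ± 0.32 for ZNF780B (limma, adjusted p from 0.00499 to 0.0347). MT3 is a metallothionein. PILRB overlaps a readthrough transcript, NAIP has near-identical copies and AHSA2P is a pseudogene, so these 3 values are uncertain. Limma called 515 genes, 147 higher and 368 lower, and 375 of them changed at least 2-fold (103 higher, 272 lower). With the replicate block it called 1631 (559 higher, 1072 lower), including all 515. The count changed strongly when 1 library was left out, also where that library was of a group not compared. It was 14 without A-485 replicate 2, 64 without A-485 replicate 1, 29 higher and 83 lower without DMSO replicate 1, 1294 without DMSO replicate 2, and between 223 and 322 without a library of the other groups. Of the 51 named genes called, 9 were called whichever library was left out (TRIM49D1, CHAC1, SLC45A3, CHRNA2, S100P, C1orf116, PSAT1 and ELOVL7 among them), and the others were lost without A-485 replicate 2. Some were also lost without other libraries, HK2, GINS2 and SIK1 in all 8 fits and SCD, INSIG1, MCM7, HEXIM1, IFI6 and AHSA2P in 7.

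By list, the ATF4 targets were the most uniform. 19 of the 23 measured members fell (21 adjusted over the list alone; camera, adjusted p = 6.59e-22, and adjusted p = 0.04997 with an estimated correlation). Among them were CHAC1 and the serine synthesis enzyme PSAT1 (-2.43 ± 0.21), and the median was -1.55. Of the androgen activity score, 9 of the 20 fell (11 adjusted over the list alone; camera, adjusted p = 1.56e-08, and adjusted p = 0.04997 with an estimated correlation). They included C1orf116. Of the other androgen-induced genes 8 of the 24 fell (12 adjusted over the list alone; camera, adjusted p = 4.24e-09, and adjusted p = 0.0534 with an estimated correlation). SLC45A3 and the cold-sensing channel TRPM8 (-2.15 ± 0.20) were among them. In the endoplasmic reticulum list 7 of the 21 fell (14 adjusted over the list alone, 13 over all genes with the replicate block; camera, adjusted p = 5.24e-09, and adjusted p = 0.04997 with an estimated correlation). HERPUD1, a degradation factor, was at -1.65 ± 0.19 and the unfolded protein response factor XBP1 at -1.44 ± 0.21. 5 of the 24 MYC and ribosome biogenesis genes fell (14 adjusted over the list alone, 14 over all genes with the replicate block; camera, adjusted p = 3.61e-07, and adjusted p = 0.04997 with an estimated correlation). They were MYC, NOLC1, ODC1, PPAN and the pseudouridine synthase gene DKC1 (-1.03 ± 0.16). 5 of the 14 glucocorticoid-responsive genes fell (7 adjusted over the list alone; camera, adjusted p = 9.17e-06, and adjusted p = 0.0782 with an estimated correlation). These were ERRFI1, FKBP5, LCN2, S100P and the leucine zipper gene TSC22D3 (-1.77 ± 0.20). No ribosomal protein gene was called by limma over all genes or adjusted over the list alone. With the replicate block 13 of the 34 were lower over all genes and 28 adjusted over the list alone. The list median was -0.59 (camera, adjusted p = 1.59e-06, and adjusted p = 0.275 with an estimated correlation), and -0.33 after correction for length and GC content with the block (camera, adjusted p = 6.15e-05).

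Smaller counts stood behind the remaining lists called with A-485. Of the genes of luminal secretory metabolism 4 of the 18 fell (7 adjusted over the list alone; camera, adjusted p = 0.000220, and adjusted p = 0.135 with an estimated correlation). They were ODC1, SLC30A4, the prostatic acid phosphatase gene ACPP (-1.83 ± 0.24) and AZGP1 (-1.18 ± 0.18). 3 of the 12 prostate transcription factors fell (4 adjusted over the list alone; camera, adjusted p = 0.00165, and adjusted p = 0.0782 with an estimated correlation). SPDEF and XBP1 were among them. 2 of the 29 G1/S genes fell, GINS2 (-0.99 ± 0.21) and the helicase subunit MCM7 (-0.81 ± 0.18). Of the list, adjusted over the list alone, 9 were lower and 1 higher. Over all genes with the block 8 were lower (camera, adjusted p = 5.43e-05, and adjusted p = 0.138 with an estimated correlation). In lipid synthesis, 2 of the 24 cholesterol genes fell, among them INSIG1 (-0.98 ± 0.19), with 3 adjusted over the list alone, 5 over all genes with the replicate block. The cholesterol list had an adjusted p of 0.00308 by camera, and adjusted p = 0.0782 with an estimated correlation. 2 of the 17 fatty acid genes fell, the elongase ELOVL7 (-2.01 ± 0.23) and the desaturase SCD (-1.13 ± 0.21). Adjusted over the list alone 6 were lower and 1 higher. Over all genes with the block 6 were lower (camera, adjusted p = 0.00529, and adjusted p = 0.0917 with an estimated correlation). Oxidative phosphorylation was lower by camera with 0 of 29 genes called by limma, and 1 higher and 4 lower with the block (camera, adjusted p = 0.00634, and adjusted p = 0.479 with an estimated correlation). The CREB targets were lower as a list (median -0.25, 12 of 14 below 0), with ATF3 (-2.02 ± 0.21) and SIK1 (-0.83 ± 0.19) called. Lower were 4 adjusted over the list alone and 4 over all genes with the block (camera, adjusted p = 0.0172, and adjusted p = 0.161 with an estimated correlation). In the hypoxia list the hexokinase HK2 fell (-1.0 ± 0.21). Lower were 2 adjusted over the list alone and 4 over all genes with the block (camera, adjusted p = 0.0413, and adjusted p = 0.161 with an estimated correlation). Of the p53 targets GDF15 (-1.34 ± 0.19) and SESN2 (-1.20 ± 0.19) fell, which ATF4 also induces. Adjusted over the list alone 7 were lower and 1 higher. Over all genes with the block 7 were lower and 2 higher (camera, adjusted p = 0.0416, and adjusted p = 0.330 with an estimated correlation).

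Among bromodomain proteins and genes that respond to BET bromodomain inhibitors, 3 of the 21 rose (4 adjusted over the list alone; camera, adjusted p = 0.00266, and adjusted p = 0.173 with an estimated correlation). They were HEXIM1, SMARCA2 and SERPINI1 (1.74 ± 0.23). Of the 29 interferon response genes, IFIT1, IFI6 (0.99 ± 0.18) and the STAT partner IRF9 (1.33 ± 0.22) rose and ISG20 fell (-1.05 ± 0.18). Adjusted over the list alone 5 were higher and 2 lower (camera, adjusted p = 0.00722, and adjusted p = 0.252 with an estimated correlation). The acetylation enzymes were higher as a list with 0 of 27 called by limma, and 1 higher and 1 lower with the block (camera, adjusted p = 0.0335, and adjusted p = 0.275 with an estimated correlation). Camera called 19 lists, 3 higher and 16 lower. With an estimated correlation 4 held, the ATF4, androgen activity score, MYC and endoplasmic reticulum lists. Left-out libraries ended some of these calls. That of p53 was lost in 7 of the 8 fits (adjusted p up to 0.0825), and that of hypoxia without DMSO replicate 1 or 2 or A-485 replicate 1 (up to 0.0876). CREB was lost without DMSO or A-485 replicate 2 (up to 0.0826), interferon and oxidative phosphorylation without A-485 replicate 1 (0.135 each), and the acetylation enzymes without A-485 replicate 1 or DMSO replicate 2 (up to 0.174). With the replicate block the hypoxia call was lost (camera, adjusted p = 0.0675).

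With both inhibitors KLK3 and KLK2 fell most of the named genes. KLK3 went from 2099 to 51.1 scaled FPKM, a log2 fold change of -5.33 ± 0.18 against DMSO (n = 2 per group; limma, adjusted p = 2.02e-05). KLK2 went from 452 to 11.1 (-5.24 ± 0.26; limma, adjusted p = 0.000158). TMPRSS2, MYC, FKBP5 and CCND1 fell as well. Their log2 fold changes were -3.70 ± 0.20 for TMPRSS2, -3.62 ± 0.20 for MYC, -1.26 ± 0.17 for FKBP5 and -1.0 ± 0.17 for CCND1 (limma, adjusted p from 0.000158 to 0.0125). HEXIM1 rose by 1.97 ± 0.17 (limma, adjusted p = 0.000819). CDKN1A (-0.93 ± 0.31; limma, adjusted p = 0.0945) was called only with the replicate block (adjusted p = 0.00522). EP300 (0.60 ± 0.22) and CREBBP (0.57 ± 0.29) were not called either way, and ranged from 0.33 to 0.86 and from 0.12 to 1.01 with 1 library left out. Besides KLK3, KLK2, TMPRSS2 and MYC, the genes that fell most were ADAMTS1, C1orf116, ACPP and CHRNA2. Log2 fold changes were -4.15 ± 0.30 for ADAMTS1, -3.73 ± 0.20 for C1orf116, -3.60 ± 0.24 for ACPP and -3.56 ± 0.28 for CHRNA2 (limma, adjusted p from 0.000158 to 0.000628). Besides HEXIM1, those that rose most were IFI27L2, AMIGO3, MT3, DPP3, SNORC, OPTN, which encodes an autophagy receptor, and the complement protease gene C1R. They rose by 3.39 ± 0.28 for IFI27L2, 3.31 ± 0.37 for AMIGO3, 3.14 ± 0.34 for MT3 and 2.72 ± 0.25 for DPP3, and by 2.52 ± 0.53 for SNORC, 2.51 ± 0.24 for OPTN and 2.05 ± 0.53 for C1R (limma, adjusted p from 0.000742 to 0.0488).

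Limma called 1233 genes with both inhibitors, 418 higher and 815 lower, and 744 of them changed at least 2-fold (201 higher, 543 lower). With the replicate block it called 2436 (1014 higher, 1422 lower), including all 1233. The count was 264 without the first and 300 without the second library of the combination, and between 833 and 1275 without any other library. Of the 61 named genes called, 38 were called whichever library was left out, among them KLK3, KLK2, TMPRSS2, MYC and HEXIM1, and the others were lost without a library of the combination. Some were also lost without a library of another group, PDK1 in all 8 fits, BCL3 and ALDOC in 7, VEGFA and C1R in 5, SYP in 4 and MYBL2, ELOVL7 and ISG20 in 3. With 1 library left out the log2 fold change ranged from 1.35 to 2.75 for C1R and 1.55 to 3.52 for SNORC.

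**Figure D1:**
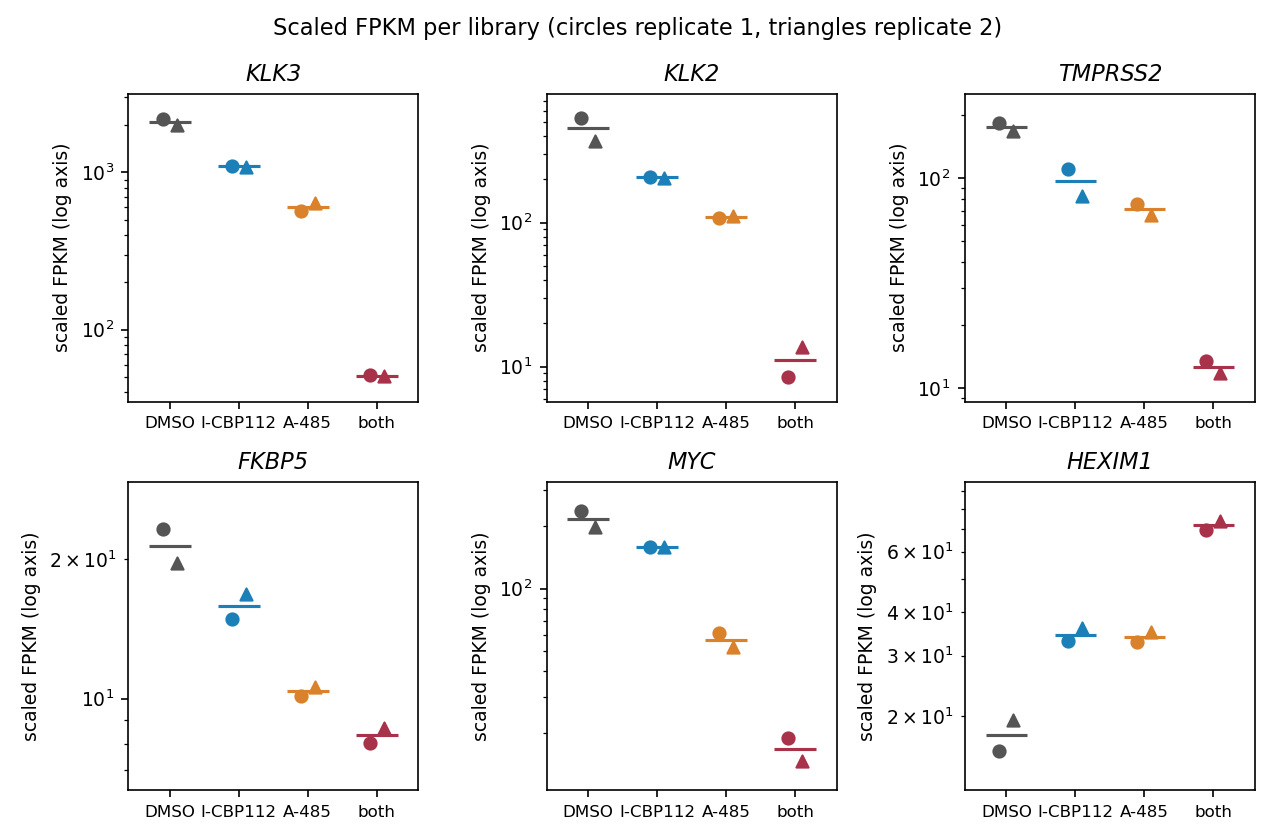
Scaled FPKM (log axis) of KLK3, KLK2, TMPRSS2, FKBP5, MYC and HEXIM1 in the 4 groups, with circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2 libraries. KLK3 lies at 2099 with DMSO, 1092 with I-CBP112, 603 with A-485 and 51.1 with both.

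Lists of the androgen programme fell with the combination. 12 of the 20 genes of the androgen activity score fell (13 adjusted over the list alone; camera, adjusted p = 2.15e-12, and adjusted p = 0.0317 with an estimated correlation), with a median of -1.24. 16 of the 24 other androgen-induced genes fell (18 adjusted over the list alone; camera, adjusted p = 6.37e-16, and adjusted p = 0.0317 with an estimated correlation). They included the potassium channel KCNN2 (-3.45 ± 0.20) and the amino acid transporter SLC43A1 (-2.86 ± 0.20). 6 of the 12 prostate transcription factors fell, among them the ETS factor SPDEF (-2.42 ± 0.24). Adjusted over the list alone 7 were lower and 1 higher (camera, adjusted p = 6.02e-05, and adjusted p = 0.0414 with an estimated correlation). The androgen-repressed genes, which androgen lowers in prostate cells, were lower too. 7 of the 14 fell and none rose, including the decarboxylase gene DDC (-3.34 ± 0.25) and CAMK2N1 (-2.12 ± 0.21). In that list 9 were lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.000227, and adjusted p = 0.157 with an estimated correlation). 7 of the 14 glucocorticoid-responsive genes fell, including TSC22D3 (-2.43 ± 0.20) and S100P (-2.13 ± 0.21). Adjusted over the list alone 7 were lower and 1 higher (camera, adjusted p = 5.27e-06, and adjusted p = 0.0596 with an estimated correlation). In luminal secretory metabolism 5 of the 18 fell (6 adjusted over the list alone, 8 over all genes with the replicate block; camera, adjusted p = 0.00279, and adjusted p = 0.198 with an estimated correlation). They were ACPP, AZGP1, SLC30A4, SRM and AMD1, a decarboxylase of polyamine synthesis (-2.04 ± 0.19).

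Genes of proliferation and of stress responses fell as well. 22 of the 29 G1/S genes fell (24 adjusted over the list alone; camera, adjusted p = 1.31e-17, and adjusted p = 0.0317 with an estimated correlation). The replicative helicase subunits MCM5 (-2.10 ± 0.19) and MCM7 (-2.10 ± 0.18) had the lowest p. 8 of the 30 G2/M genes fell (8 adjusted over the list alone; camera, adjusted p = 1.62e-05, and adjusted p = 0.150 with an estimated correlation). MYBL2 (-1.40 ± 0.27) and the kinase AURKB (-1.23 ± 0.21) were among them. 10 of the 24 MYC and ribosome biogenesis genes fell (18 adjusted over the list alone; camera, adjusted p = 1.52e-11, and adjusted p = 0.0317 with an estimated correlation), including the nucleolar NOLC1 (-1.36 ± 0.16). 21 of the 23 ATF4 targets fell (21 adjusted over the list alone; camera, adjusted p = 5.08e-19, and adjusted p = 0.0317 with an estimated correlation), with CHAC1 at -2.59 ± 0.22 and PSAT1 at -2.30 ± 0.21. 10 of the 21 endoplasmic reticulum genes fell (15 adjusted over the list alone; camera, adjusted p = 5.41e-09, and adjusted p = 0.0317 with an estimated correlation), with XBP1 at -1.91 ± 0.21 and HERPUD1 at -1.56 ± 0.19. 10 of the 24 p53 targets fell (13 adjusted over the list alone; camera, adjusted p = 1.30e-06, and adjusted p = 0.0831 with an estimated correlation). They included GDF15 (-2.29 ± 0.19) and the nuclease AEN (-1.43 ± 0.20). Limma called 0 of the 34 ribosomal protein genes over all genes and 0 adjusted over the list alone. As a list they were lower (median -0.35, camera, adjusted p = 0.00279, and adjusted p = 0.472 with an estimated correlation).

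Of the interferon response genes, IFI6 (1.17 ± 0.18), IRF9 (1.61 ± 0.22), PSMB9 and STAT2 rose with both inhibitors and ISG20 fell (-0.92 ± 0.18). With p adjusted over the list alone 7 were higher and 2 lower. Over all genes with the block 8 were higher and 1 lower (camera, adjusted p = 0.00565, and adjusted p = 0.265 with an estimated correlation). Of the bromodomain list HEXIM1 and the histone gene HIST2H2BE (1.32 ± 0.22) rose (3 adjusted over the list alone; camera, adjusted p = 0.0155, and adjusted p = 0.265 with an estimated correlation). Of the acetylation enzymes the acetyltransferase KAT2B rose (1.01 ± 0.18; 1 adjusted over the list alone, 4 over all genes with the replicate block and 1 lower; camera, adjusted p = 0.0332, and adjusted p = 0.265 with an estimated correlation). Camera called 16 lists, 3 higher and 13 lower. With an estimated correlation 7 held, those of the androgen-induced genes (both lists), prostate transcription factors, G1/S, MYC, ATF4 and the endoplasmic reticulum. Lost with 1 library left out were the calls of the acetylation enzymes (first library of the combination or DMSO replicate 2, adjusted p up to 0.0949) and of ribosomal proteins (first library of the combination, 0.0949). Those of bromodomain proteins and secretory metabolism were lost without DMSO replicate 1 (adjusted p = 0.149 and 0.105).

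**Figure D2:**
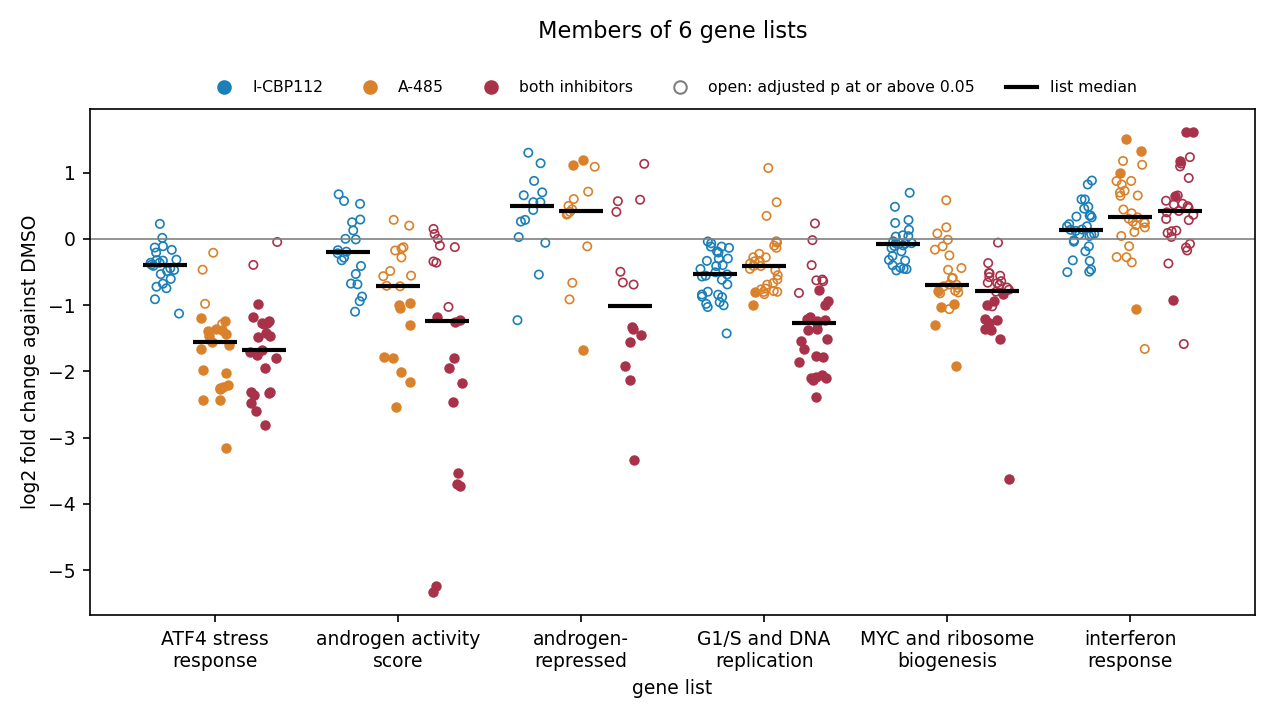
Log2 fold change against DMSO of each measured member of 6 gene lists with I-CBP112, A-485 and both, filled where limma's adjusted p was under 0.05, with a black bar at the median. The G1/S medians were -0.54, -0.41 and -1.26, and those of the ATF4 targets -0.39, -1.55 and -1.68.

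The genes called with A-485 and with the combination overlapped in 74 that rose and 301 that fell in both. Simulations without any effect drew all libraries anew, with the DMSO libraries shared by both comparisons. They gave 0.03 shared calls on average and at most 1 in each direction. Almost no gene is called without an effect, so these counts could not show what the shared controls add. Independent lists of these sizes would share 5.18 and 25.3. The log2 fold changes correlated across genes with r = 0.75 (simulated 0.50), and genes are not independent replicates. Their covariance was 0.249 against a simulated 0.0427, a difference of 0.206. With only 2 DMSO libraries the controls were not split, so part of the excess of shared calls over independent lists may come from the shared controls. A single gene was called in opposite directions, TM4SF1, a tetraspanin-like surface protein, which rose with A-485 (1.81 ± 0.27; limma, adjusted p = 0.0152) and fell with both (-1.64 ± 0.27; limma, adjusted p = 0.00970).

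Set against I-CBP112 alone, the combination lowered KLK3 further, by a log2 fold change of -4.39 ± 0.18 (n = 2 per group; limma, adjusted p = 9.33e-05). The others that fell most had log2 fold changes of -4.14 ± 0.26 for KLK2, -3.89 ± 0.25 for DDC, -3.56 ± 0.20 for C1orf116 and -3.45 ± 0.30 for ADAMTS1 (limma, adjusted p from 0.000359 to 0.00188). Those that rose most were at 2.12 ± 0.37 for AMIGO3, 1.70 ± 0.25 for VPS9D1, 1.70 ± 0.28 for IFI27L2, 1.69 ± 0.25 for B3GALT4 and 1.60 ± 0.29 for MT1F, a metallothionein (limma, adjusted p from 0.0159 to 0.0351). 10 of the 20 genes of the androgen activity score fell (15 adjusted over the list alone; camera, adjusted p = 7.88e-19, and adjusted p = 0.0193 with an estimated correlation). 11 of the 24 other androgen-induced genes fell (18 adjusted over the list alone; camera, adjusted p = 1.34e-20, and adjusted p = 0.0193 with an estimated correlation). 6 of the 14 androgen-repressed genes fell (11 adjusted over the list alone; camera, adjusted p = 1.30e-11, and adjusted p = 0.0390 with an estimated correlation). 12 of the 23 ATF4 targets fell (20 adjusted over the list alone, 19 over all genes with the replicate block; camera, adjusted p = 5.96e-21, and adjusted p = 0.0363 with an estimated correlation). 10 of the 29 G1/S genes fell (18 adjusted over the list alone; camera, adjusted p = 5.45e-13, and adjusted p = 0.0390 with an estimated correlation), and so did 6 of the 24 MYC and ribosome biogenesis genes (15 adjusted over the list alone, 15 over all genes with the replicate block). The MYC list had an adjusted p of 4.75e-15 by camera, and adjusted p = 0.0193 with an estimated correlation. Limma called 275 genes, 33 higher and 242 lower, or 696 with the replicate block (174 higher, 522 lower). Camera called 15 lists, 1 higher (interferon) and 14 lower, 8 of them with an estimated correlation. With the block the ribosomal protein list was also called, lower (camera, adjusted p = 0.102 without and 0.00946 with it). The gene count was 43 or 59 without a library of the combination, 62 or 57 without an I-CBP112 library and 142 or 141 without an A-485 library. Of the 10 named genes, KLK3, KLK2, DDC, C1orf116 and ADAMTS1 were called whichever library was left out. The list calls of interferon (I-CBP112 replicate 1, adjusted p = 0.0501), G2/M (second library of the combination, 0.0578) and cholesterol (either of these, up to 0.0587) were lost. With an estimated correlation these were lost too (adjusted p = 0.220, 0.320 and 0.121).

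Set against A-485 alone, the combination lowered KLK3 and KLK2 further, with log2 fold changes of -3.53 ± 0.18 and -3.23 ± 0.26 (n = 2 per group; limma, adjusted p from 0.000513 to 0.00373). HGD, an enzyme of tyrosine breakdown, and COLCA1 fell too, at -3.15 ± 0.33 for HGD and -2.78 ± 0.22 for COLCA1. Those that rose most were at 1.87 ± 0.28 for IFI27L2, 1.46 ± 0.19 for TLE1, 1.36 ± 0.20 for CNPY4, 1.21 ± 0.19 for CBLN2 and 1.34 ± 0.19 for INSIG1 (limma, adjusted p from 0.00373 to 0.0357 over these 7). CDC6, MCM5, MCM7 and RRM2 were the 4 of the 29 G1/S genes that fell (22 adjusted over the list alone, 9 over all genes with the replicate block). The G1/S list had an adjusted p of 1.26e-20 by camera, and adjusted p = 0.0439 with an estimated correlation. CDK1 was the 1 of 30 G2/M genes that fell, with 17 adjusted over the list alone. Over all genes with the block 2 fell, CDK1 and CCNA2 (camera, adjusted p = 4.13e-15, and adjusted p = 0.0439 with an estimated correlation). 7 of the 20 genes of the androgen activity score fell, with 9 lower and 2 higher adjusted over the list alone (camera, adjusted p = 6.31e-09, and adjusted p = 0.0439 with an estimated correlation). 6 of the 14 androgen-repressed genes fell (9 adjusted over the list alone; camera, adjusted p = 2.07e-12, and adjusted p = 0.0439 with an estimated correlation). KLK4 and KCNN2 were the 2 of the 24 other androgen-induced genes that fell (13 adjusted over the list alone, 5 over all genes with the replicate block; camera, adjusted p = 1.83e-09, and adjusted p = 0.0439 with an estimated correlation). The cholesterol genes were higher than with A-485 alone, with INSIG1 the 1 of 24 called (1 adjusted over the list alone; median 0.23, camera, adjusted p = 0.000339, and adjusted p = 0.0468 with an estimated correlation). For the ATF4 targets the median was -0.05 and no difference was called (camera, adjusted p = 0.825), from which no likeness is concluded. Limma called 98 genes, 12 higher and 86 lower, or 174 with the replicate block (44 higher, 130 lower), 97 of them in both fits. Camera called 11 lists, 3 higher and 8 lower, 7 of them with an estimated correlation. The gene count was 14 or 17 without a library of the combination, 35 or 9 without A-485 replicate 1 or 2, and 52 without either I-CBP112 library. KLK3, KLK2 and COLCA1 were the 3 of 10 named genes called whichever library was left out. The calls of ribosomal proteins and oxidative phosphorylation, both higher (0.0142 and 0.00791 by camera), were lost without A-485 replicate 1 or the second library of the combination (adjusted p up to 0.476 and 0.484). They were lost with an estimated correlation as well (adjusted p = 0.622 and 0.590), as were those of prostate transcription factors and p53 targets (adjusted p = 0.0639 and 0.0940).

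Set against each other, A-485 left lower levels than I-CBP112 of TRIM49D1, SLC45A3, the heparan sulfotransferase HS3ST1, CHAC1 and HES6. Log2 fold changes of A-485 over I-CBP112 were -3.18 ± 0.20 for TRIM49D1, -3.13 ± 0.23 for SLC45A3, -3.00 ± 0.24 for HS3ST1, -2.95 ± 0.22 for CHAC1 and -2.41 ± 0.30 for HES6 (n = 2 per group; limma, adjusted p from 0.00271 to 0.0168). The secreted phospholipase PLA2G2A was higher (1.96 ± 0.22), and so were NAIP, SERPINI1, IER5L and RAB19. These were at 1.65 ± 0.21 for NAIP, 1.58 ± 0.23 for SERPINI1, 1.44 ± 0.23 for IER5L and 1.26 ± 0.19 for RAB19 (limma, adjusted p from 0.0129 to 0.0399). 7 of the 23 ATF4 targets were lower (19 adjusted over the list alone, 17 over all genes with the replicate block; camera, adjusted p = 2.63e-22, and adjusted p = 0.0324 with an estimated correlation). In lipid synthesis INSIG1 was the 1 of 24 cholesterol genes called (8 adjusted over the list alone, 8 over all genes with the replicate block; camera, adjusted p = 6.78e-07, and adjusted p = 0.0324 with an estimated correlation), with the median at -0.34. ELOVL7 and SCD were the 2 of 17 fatty acid genes called (8 adjusted over the list alone, 5 over all genes with the replicate block; camera, adjusted p = 3.08e-07, and adjusted p = 0.0324 with an estimated correlation). C1orf116, MAF and PMEPA1 were among the 4 of the 20 genes of the androgen activity score that were lower (9 adjusted over the list alone; camera, adjusted p = 4.42e-08, and adjusted p = 0.0452 with an estimated correlation). MYC was the 1 of 24 MYC and ribosome biogenesis genes called (10 adjusted over the list alone, 7 over all genes with the replicate block; camera, adjusted p = 3.68e-08, and adjusted p = 0.0324 with an estimated correlation). The G2/M genes were higher with A-485 than with I-CBP112. Limma called 0 of 30, 0 adjusted over the list alone and 1 (FOXM1) over all genes with the block (median 0.54, camera, adjusted p = 4.42e-08, and adjusted p = 0.0913 with an estimated correlation). Limma called 102 genes, 10 higher and 92 lower, or 347 with the replicate block (62 higher, 285 lower). Camera called 14 lists, 2 higher and 12 lower, 5 of them with an estimated correlation. The block added oxidative phosphorylation, lower (camera, adjusted p = 0.0586 without and 0.00977 with it). Between 5 and 12 genes were called without a library of either group, and 52 without either library of the combination. TRIM49D1, SLC45A3 and CHAC1 were the 3 of 10 named genes called whichever library was left out. The list calls of prostate transcription factors (I-CBP112 replicate 1, adjusted p = 0.0882), interferon (replicate 1 of either group, up to 0.324) and ribosomal proteins (I-CBP112 replicate 2, 0.0614) were lost. None of the 3 held with an estimated correlation (adjusted p = 0.139, 0.319 and 0.407).

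The interaction asked whether the combination departed from the sum of the changes with each inhibitor on the log2 scale. For KLK3 the sum was -2.74 and the change with both -5.33 ± 0.18, a difference of -2.59 ± 0.25 (n = 2 per group; limma, adjusted p = 0.0737, and 0.0197 with the replicate block). For 8 others of the 10 genes called with the block the difference was -2.40 ± 0.30 for UGT2B17, -2.32 ± 0.24 for BCHE, -2.30 ± 0.32 for UGT2B15, -2.28 ± 0.33 for TFPI and -2.21 ± 0.35 for DDC. Smaller ones were -2.06 ± 0.23 for MAOA, -2.05 ± 0.26 for ACKR3 and -1.81 ± 0.24 for PLK2 (limma, adjusted p from 0.0737 to 0.141 without and from 0.0197 to 0.0457 with the block). UGT2B15 and UGT2B17 are near-identical paralogs that inactivate androgens, so that their separate values are uncertain, BCHE is a cholinesterase, MAOA degrades monoamines and ACKR3 is a chemokine receptor. All 9 lay below the additive value, and they were picked because of the blocked result. The differences for KLK2 (-2.13 ± 0.37), TMPRSS2 (-1.53 ± 0.28) and MYC (-1.25 ± 0.28) were not called either way, with adjusted p from 0.177 to 0.328. Without the block limma called 0 of 11871 genes, and 0 with any library left out, although 1058 had an unadjusted p under 0.05 (1841 with the block, which called 10). Voom on approximate fragments called 31 genes, or 168 with the block.

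As lists, the androgen-repressed genes lay below the additive value in all 14 measured members, in 13 of them in both same-numbered pairs, with a median interaction of -1.85. Limma called 0 over all genes, 5 with the block and 10 adjusted over the list alone (camera, adjusted p = 2.11e-14, and adjusted p = 0.171 with an estimated correlation). Of these 14 genes, 11 lay above DMSO with I-CBP112, 10 with A-485 and 4 with both. The androgen activity score was below the additive value too (median -0.55, camera, adjusted p = 1.55e-05, and adjusted p = 0.203 with an estimated correlation). Here limma called 0 over all genes, 1 with the block (KLK3) and 7 adjusted over the list alone. So were the other androgen-induced genes (median -0.32, 3 adjusted over the list alone; camera, adjusted p = 0.00175, and adjusted p = 0.319 with an estimated correlation). The G1/S genes (-0.37; camera, adjusted p = 0.00140, and adjusted p = 0.319 with an estimated correlation) and the G2/M genes (-0.21; camera, adjusted p = 0.000621, and adjusted p = 0.319 with an estimated correlation) were also below it, with none called adjusted over the list alone. Above it were the ATF4 targets (0.44; camera, adjusted p = 9.13e-05, and adjusted p = 0.319 with an estimated correlation) and the endoplasmic reticulum genes (0.32; camera, adjusted p = 0.000625, and adjusted p = 0.299 with an estimated correlation). The ribosomal proteins (0.40; camera, adjusted p = 0.000621, and adjusted p = 0.443 with an estimated correlation) and oxidative phosphorylation (0.36; camera, adjusted p = 0.00140, and adjusted p = 0.443 with an estimated correlation) lay above it as well. For the glucocorticoid-responsive genes, with 2 adjusted over the list alone, the median was 0.23 (camera, adjusted p = 0.0442, and adjusted p = 0.333 with an estimated correlation). Camera called 10 lists, 5 in each direction, and 0 with an estimated correlation. With the block the glucocorticoid call was lost (camera, adjusted p = 0.0894) and the MYC list was called, lower (adjusted p = 0.0763 without and 0.0448 with it). With 1 library left out the other androgen-induced and G1/S calls were lost without DMSO replicate 2 (adjusted p = 0.122 and 0.0696). The ribosomal protein and oxidative phosphorylation calls were lost without I-CBP112 or A-485 replicate 1, and the latter also without the second library of the combination (up to 0.126 and 0.139). The glucocorticoid call was lost in 5 of the 8 fits, without either library of the combination or replicate 1 of any other group (up to 0.253).

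**Figure D3:**
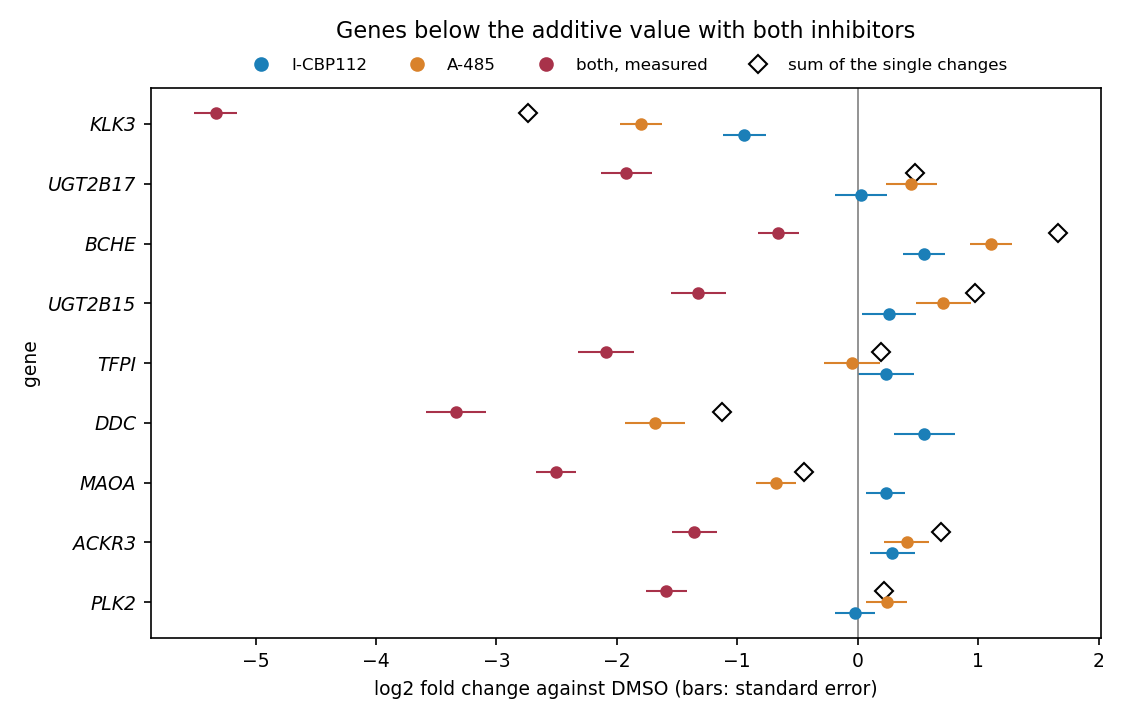
Log2 fold change against DMSO (± SE, n = 2 libraries per group) of 9 genes whose interaction passed with the replicate block, with I-CBP112, A-485 and both. The SE is that of the fit without the block, and an open diamond marks the sum of the single changes. The value with both lies left of the diamond for each gene, at -0.66 against 1.66 for BCHE.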

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

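The results below were picked out because the effect of A-485 appeared to differ with and without I-CBP112. The tests of length and GC content and of paralogs were fixed before their results were seen, while that of scaling and the genes and lists concerned were chosen after the result was seen. With the replicate block the interaction was called for KLK3 (-2.59 ± 0.25), UGT2B17 (-2.40 ± 0.30), BCHE (-2.32 ± 0.24) and UGT2B15 (-2.30 ± 0.32). It was also called for TFPI (-2.28 ± 0.33), DDC (-2.21 ± 0.35), MAOA (-2.06 ± 0.23), ACKR3 (-2.05 ± 0.26) and PLK2 (-1.81 ± 0.24), each on the log2 scale (limma with the block, adjusted p from 0.0197 to 0.0457). Without the block, the model fixed beforehand, limma called 0 of 11871 genes, with adjusted p from 0.0737 to 0.141 for these genes. The standard errors given with these genes are those of the fit without the block. Camera called 10 lists in the interaction, given with their medians. Below the additive value were the androgen-repressed genes (-1.85), the androgen activity score (-0.55), the other androgen-induced genes (-0.32), G1/S (-0.37) and G2/M (-0.21). Above it were the ATF4 targets (0.44), the endoplasmic reticulum genes (0.32), the glucocorticoid-responsive genes (0.23), oxidative phosphorylation (0.36) and the ribosomal proteins (0.40). None of these was called with an estimated correlation.

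A further 10 of the genes named here went in opposite directions in every pair with A-485 added to DMSO and added to I-CBP112, and limma's interaction test did not pass for any of them, with or without the block. Added to DMSO and to I-CBP112, A-485 changed BTG2 by 0.31 and -0.78, CCNA2 by 0.48 and -0.44 and CDK1 by 0.62 and -0.58. The values were 0.32 and -2.08 for COLCA1, 0.13 and -1.70 for HGD, -0.61 and 1.60 for MT1F and 0.39 and -0.81 for PLA2G2A. RNF167 was at -0.15 and 0.24, SESN3 at 1.19 and -0.13 and TM4SF1 at 1.81 and -0.67. For several genes 1 of the 2 values was small, so the opposite signs alone do not show a reversal. The interaction was -1.10 ± 0.26 for BTG2, -0.92 ± 0.34 for CCNA2, -1.20 ± 0.38 for CDK1, -2.40 ± 0.31 for COLCA1, -1.83 ± 0.46 for HGD, 2.21 ± 0.41 for MT1F, -1.19 ± 0.31 for PLA2G2A, 0.39 ± 0.36 for RNF167, -1.32 ± 0.26 for SESN3 and -2.48 ± 0.38 for TM4SF1, with adjusted p from 0.0951 to 0.771 and, with the block, from 0.0631 to 0.505.

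The pattern weighed is that of the androgen-repressed genes, of which 11 of 14 lay above DMSO with I-CBP112 and 10 with A-485, against 4 with both, although limma called none of them higher with I-CBP112 and BCHE and SESN3 with A-485 (4 with the block, and 3 lower). The data argued against transcript length or GC content and against reads shared between the UGT2B paralogs as causes. After removal of each library's trend with transcript length and GC content the median interaction was -1.57 (camera, adjusted p = 3.23e-13). Without the UGT2B paralogs it was -1.32 over 11 members. On the FPKM as deposited, without the scaling applied here, it was -1.60. Scaling uses 1 factor per library and moved the median interaction of all genes only from 0.20 to 0.01. The test of scaling could therefore hardly have come out otherwise, and it decides nothing. The camera call was lost with an estimated correlation (adjusted p = 0.171), and a spread between cultures beyond that of 2 libraries per group stays open. A biological difference between blocking 1 and both sites of p300 and CBP also stays open as a hypothesis found on these data, and it was not tested.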

How the results depend on the processing

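The FPKM as deposited, pseudocounts, voom fits, library weights and length and GC correction were chosen after the data had been seen. Unless stated, counts are of genes called by limma, given in the order A-485 against DMSO, both against DMSO, both against I-CBP112, both against A-485, A-485 against I-CBP112, and the cause of a change was not tested. The counts for median-of-ratios and upper quartile scaling and for pseudocounts of 0.1 and 5 stayed within 1.5 times of those reported, and no other scaling moved the share of higher against lower calls by over 10 percentage points. On the FPKM as deposited, 0 genes were called in each of the 5 comparisons. The totals of same-group libraries then differed, at 808443 and 187776 with DMSO and 766588 and 408673 with both. No scaling or block took this difference out of the spread. The replicate block gave 1631, 2436, 696, 174 and 347 genes and 10 in the interaction, and changed no list call beyond the 5 given with the results. It left 169 calls of named genes the same, called 14 more and lost 0. The block with length and GC correction gave 1678, 3055, 1047, 291 and 494, with 24 for I-CBP112 against DMSO and 12 in the interaction. It ended the camera calls of ribosomal proteins with I-CBP112 (adjusted p = 0.199), between both and A-485 (0.868) and in the interaction (0.276, median 0.10), of the hypoxia and CREB lists with A-485 (0.0703 each) and of the glucocorticoid-responsive genes in the interaction (0.164). Newly called with it were ribosomal proteins between both and I-CBP112 (0.000236), fatty acid synthesis between both and A-485 (0.0212) and MYC in the interaction (0.00191). Further medians of called lists that moved by over 1.5 times became 0.15 for the acetylation enzymes with A-485, 0.12 for oxidative phosphorylation between both and A-485, -0.17 for ribosomal proteins between A-485 and I-CBP112, and in the interaction -0.42 for G2/M and 0.21 for oxidative phosphorylation. Of the named genes it also called HEXIM1 with I-CBP112, EP300 with A-485 and with both, and TMPRSS2 in the interaction, where UGT2B17 and TFPI were no longer called. Voom on approximate fragments gave 1727, 2309, 528, 260 and 307, with 31 in the interaction. With the block it gave 4124, 4318, 1681, 1217 and 1287, with 383 for I-CBP112 and 168 in the interaction. Library weights changed A-485 against DMSO to 194 and the last 3 comparisons to 574, 206 and 200. The weights, lower where libraries vary more, were 0.559 for each DMSO library, 1.062 for I-CBP112, 1.123 for A-485 and 1.501 for the combination. The spread shared by the groups may therefore understate the standard errors of comparisons with DMSO and overstate those of comparisons without it. Weights from 2 libraries per group are themselves uncertain. No filter on low values gave 342 for A-485 against DMSO and 161, 59 and 40 for the last 3. A minimum mean of 5 called 1 gene with I-CBP112 (DPP3) and 4 in the interaction (BCHE, KLK3 and MAOA among them). Fits on only the 2 groups compared, with fewer samples behind the spread, gave 95, 627 and 145 for the first 3. A minimum log2 change of 1 left 744 for both against DMSO. With 31830 isoforms tested singly, the genes with at least 1 isoform that passed numbered 0, 97, 33, 0 and 3. There were 7 with I-CBP112 (EEF1D, RNF167, SHMT2, EEF1B2, ACADVL, SSBP1 and MPV17) and 1 in the interaction (EEF1D). The 3 genes were EEF1D, EEF1B2 and MPV17. With 1 library left out the counts ran from 14 to 1294, 264 to 1275, 43 to 350, 9 to 118 and 5 to 116, from 0 to 2 with I-CBP112 and from 0 to 0 in the interaction. The lone library of a group is then assumed to vary like the other groups. Camera called 15 to 18, 14 to 16, 14 to 16, 9 to 11 and 14 to 15 lists in these fits, 8 to 15 with I-CBP112 and 7 to 12 in the interaction. With an estimated correlation it called 4, 7, 8, 7 and 5 lists, and 0 with I-CBP112 and in the interaction. Fry, which tests whether a list moves without comparing it with other genes, called 7 lists with I-CBP112 and 3 in the interaction. The 1 called value that turned its sign was the median of the cytosolic ribosomal proteins with I-CBP112, from -0.18 as reported to 0.0352 without I-CBP112 replicate 1 (camera, adjusted p = 0.896) and -0.39 without I-CBP112 replicate 2, its extremes with 1 library left out. Changes of sign where neither value was called were counted as the same. Not run was a Wald test in DESeq2, which needs counts, and voom on counts was replaced by voom on approximate fragments. The replicate 2 libraries of DMSO, I-CBP112 and A-485, at 4.44 to 5.31 M assigned fragments (M for 1e+06), limit what can be seen of genes with low values.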

Other observations

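The tests of the length trend in DMSO replicate 1 and of the replicate 2 libraries were chosen after the result was seen, and that of length and GC content before. Some gene groups were not called as lists with both inhibitors although members changed. Among the 6 measured neuroendocrine markers, ENO2 (1.64 ± 0.23) and SYP (1.19 ± 0.26) rose while SYT4 (-2.77 ± 0.28) and the histone methyltransferase gene EZH2 (-1.33 ± 0.17) fell (camera, adjusted p = 0.330). Of the 20 apoptosis regulators, the pro-apoptotic PMAIP1 (-1.58 ± 0.20), BBC3 (-1.09 ± 0.18), BID and BIK and the survivin gene BIRC5 fell, and 1 rose with the block (camera, adjusted p = 0.358). PMAIP1 was the 1 that fell with A-485 (-1.33 ± 0.20; 1 higher and 4 lower with the block; camera, adjusted p = 0.666). The hypoxia list split, with ALDOC higher (0.82 ± 0.19) and PDK1 (-0.79 ± 0.20) and VEGFA (-0.97 ± 0.22) lower, or 3 higher and 4 lower with the block (camera, adjusted p = 0.517), and its median of 0.06 and mean of -0.12 differed in sign. Of the CREB targets ATF3, FOS, SIK1 (-1.35 ± 0.19) and BTG2 (-1.10 ± 0.19) fell, and 1 rose with the block (camera, adjusted p = 0.106), of the NF-kB targets BCL3 (-0.84 ± 0.20; 1 higher and 2 lower with the block; camera, adjusted p = 0.641), and of the basal markers LAMA3 (-1.72 ± 0.27; 1 higher with the block; camera, adjusted p = 0.555). The collagen gene COL1A1, a stromal marker, rose with A-485 (1.26 ± 0.18; camera, adjusted p = 0.986) and with both (1.39 ± 0.18; camera, adjusted p = 0.521), and the block called 1 other marker lower in each. In oxidative phosphorylation the median with both was -0.07, with 0 called by limma and 2 higher and 1 lower with the block (camera, adjusted p = 0.525).

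The lipid synthesis lists were called lower with A-485 and not with both inhibitors, and with an estimated correlation they were not called with A-485 either (cholesterol, adjusted p = 0.0782, and fatty acid, 0.0917). The cholesterol list had a median of -0.42 with A-485 and -0.01 with both (2 higher and 3 lower with the block; camera, adjusted p = 0.777), and the direct comparison of both with A-485 was called higher (median 0.23; camera, adjusted p = 0.000339, and adjusted p = 0.0468 with an estimated correlation). The fatty acid list had medians of -0.47 and -0.34, with ELOVL5 (-1.38 ± 0.19) and ELOVL7 (-1.02 ± 0.23) lower with both and 1 higher with the block (camera, adjusted p = 0.151), and the direct comparison was not called (camera, adjusted p = 0.0665). Of the androgen-repressed genes BCHE (1.11 ± 0.17) and SESN3 (1.19 ± 0.18) rose and DDC (-1.68 ± 0.25) fell with A-485. Adjusted over the list alone 4 were higher and 3 lower, and over all genes with the block 4 higher and 3 lower (camera, adjusted p = 0.0998). With A-485 the G2/M list (0.22; camera, adjusted p = 0.130) and the NF-kB, neuroendocrine and basal lists (camera, adjusted p = 0.767, 0.735 and 0.767) were not called. Of their members limma called 0, and with the block 2 of the G2/M, 1 of the NF-kB and 1 of the basal list were higher and 1 of the neuroendocrine and 1 of the basal list lower.

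Long transcripts tended to be higher with A-485: with genes split into 5 classes by transcript length, the median log2 change of the longest class exceeded that of the shortest by 0.48 in replicate 1 and by 0.22 in replicate 2. The second value argues against a length trend in the DMSO replicate 1 library as the whole cause. That library may still add to the trend, since the gap for I-CBP112 was 0.35 in replicate 1 and -0.06 in replicate 2, and for both inhibitors 0.24 and -0.05. After correction for length and GC content, with the block, 70.5% of the 559 genes called higher with A-485 were still called (394), their median log2 fold change going from 0.90 to 0.74, against 82.9% of those called lower. The share lay between the bounds set for either explanation. The correction removes a trend with length whatever its origin. No share could therefore have told bias of the libraries from a biological effect on long genes.

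The replicate 2 libraries had FPKM totals below those of replicate 1. The numbers of fragments they were normalized by overlapped, at 15.7 to 27.3 M (M for 1e+06) in replicate 2 and 17.1 to 31.0 M in replicate 1. FPKM are divided by this number, so shallower sequencing would not by itself lower their total. The overlap therefore says nothing on the cause of the low totals. The share assigned to the transcripts of the table was at most 49.4% in replicate 2. Fragments outside these transcripts, such as ribosomal or intronic RNA, may make up the rest, which cannot be told apart from other losses because no other features are used here. Within replicate 2 the share also differed between the groups, at 22.6% with DMSO, 21.5% with I-CBP112, 33.8% with A-485 and 49.4% with both, and no biological explanation was tested.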
